A study of Mus musculus with 6 samples.

How the data were processed

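The data are 6 RNA-seq libraries of mast cells sorted by flow cytometry from fetal mouse skin at embryonic day 18.5, 3 from control and 3 from prenatally stressed offspring. Each library is a pool of 4 mice and is named a biological replicate in the labels. The labels do not say how many dams or litters a pool came from, so p-values measure the spread between pools. The start of the stress is given as embryonic day 13.5 in the design text and as day 13 in the treatment protocol. Its end is given as day 18.5, the day of collection, in the design text and as day 18 in the protocol. Per the labels' protocols, the skin was minced and digested with enzymes at body temperature before sorting, and stranded, poly-A selected, paired-end libraries were made. Both sexes were used.

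The authors deposited 1 table per library with the raw count of reads per gene symbol, not normalized. FastQC, STAR 2.4 and HTSeq 0.9.1 are named in the submitters' processing notes, together with the builds GRCm39 and mm10, with no role for either. The strand setting, the annotation release and any filter are not given in the sources used here, and since the build behind these counts is open, no coordinates are printed. The tables hold 55809 gene rows and 5 rows that name no gene, which were kept out of library sizes and tests. Of all reads tallied, reads outside annotated features were 7.83% to 9.78% per library, ambiguous reads 1.77% to 1.85%, and reads without a unique alignment 8.49% to 9.00%; 79.7% to 81.4% were assigned to genes. Reads that align to more than one place are not in the gene counts, so genes with near-identical copies are undercounted or split. Gene symbols were matched to GENCODE M21, whose build is GRCm38, and to a RefSeq table for names and biotypes only; 52090 rows matched (93.3%).

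Genes were filtered with edgeR's filterByExpr (minimum count 10), which left 16716 genes, and libraries were scaled with TMM factors. The main test was edgeR 4.0.16's quasi-likelihood test (glmQLFit, glmQLFTest, R 4.3.3) of prenatal stress against control with no covariate and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 10.4%. CPM values use TMM-scaled library sizes. The 38 gene lists were fixed before the data were examined and cover mast cell functions, stress and activation responses, metabolism, and markers of other cell types that the sort could hold. Each list with at least 5 measured genes was tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the 38 lists. The same lists were tested with a correlation estimated from the data and with fry. With the estimated correlation 0 lists passed (2 had an unadjusted p under 0.05), and with fry 0 passed for a change in one direction (9 had an unadjusted p under 0.05; smallest adjusted p = 0.0503). Shares of counts were compared with exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3.

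The genes named were fixed by a rule: the 5 sort markers; the 12 largest rises and 12 largest falls among protein-coding genes that passed, with a mean of at least 5 CPM, a formal symbol and all stress libraries on one side of all controls; up to 4 called genes with the smallest p per list; and the 5 most expressed members of each mast cell list. That gave 133 genes, of which 100 passed, 38 of them also in each fit without 1 library. Not every one of them is reported here. Genes outside the rule are said to have been named after their values were seen; the macrophage genes other than the sort markers and Cx3cr1, and Mlana, Hspa1a, Dnajb1 and Hsph1, are of that kind. For each named gene, the share of its transcript sequences of 75 bases found in another gene's transcripts, and its exon overlap with other genes, were computed from GENCODE M21.

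The alternatives were RLE and upper-quartile factors, library totals only, no filter, a stricter filter (at least 10 counts in at least 3 libraries and a mean of at least 1 CPM), DESeq2 1.42.0, limma-voom with and without sample weights, the replicate number as a block, the log2 ratio of Y-linked to Xist counts as a covariate, protein-coding genes only, no haemoglobin, mitochondrial or sex-linked genes, a tested 1.5-fold change, and each library left out in turn. The macrophage covariate and stress replicate 3 alone against the controls were added after the data were seen. With 1 stress library, the fit assumes that it varies like the controls. For values that passed under neither setting, a change of sign was not counted as a reversal.

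The test was tried on counts simulated from the 16716 genes for this comparison, with 50 genes changed at each fold. It recovered 22.0% of the genes changed by 1.25-fold, 48.0% at 1.5-fold, 72.0% at 2-fold and 94.0% at 4-fold, and 13 of its 131 calls were false; with no change simulated it made 0 calls. The list test found the list that was shifted and called 0 others. Genes were simulated independently of each other, so this does not show how the list test behaves where genes vary together. Counts of libraries in the same group differed by more than sampling noise (chi-square per degree of freedom from 10.5 to 44.9), so no library was counted as a duplicate.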

Results

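Mast cells were sorted from the skin of C57BL/6J mouse fetuses at embryonic day 18.5, and their polyadenylated RNA was sequenced. Mast cells are granule-bearing immune cells of the tissue that carry the stem cell factor receptor KIT (CD117) and the interleukin 33 receptor ST2. The sort kept CD45-positive cells that carried both and lacked the macrophage markers F4/80 and CD64. In the prenatal stress group the pregnant dams were restrained in tubes under a bright light 3 times a day for 30 minutes, and control dams were left undisturbed. Each group had 3 libraries, and each library came from a pool of 4 mice, 12 mice per group. The libraries held 74735139, 54616570 and 55792766 counts assigned to genes in control replicates 1, 2 and 3, and 51710555, 57032963 and 57806119 in prenatal stress replicates 1, 2 and 3. Between 23574 and 24821 genes had at least one count in a library. Levels below are counts scaled to library size in the usual CPM unit (mean ± SD, n = 3 pools per group). Log2 fold changes are given with their standard error (SE) and are positive where the level was higher after prenatal stress. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

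The comparison asked how the transcriptome of fetal skin mast cells differed between offspring of stressed and undisturbed dams. The genes with the largest rises included several that mast cells use to sense their surroundings. Mrgprb1, a Mas-related G protein-coupled receptor, rose from 118.5 ± 33.1 to 675.5 ± 132 CPM (log2 fold change 2.51 ± 0.22, adjusted p = 0.00139). The related receptor gene Mrgprx2 rose from 28.4 ± 5.87 to 155.7 ± 36.8 (2.45 ± 0.20, adjusted p = 0.00105). Fcer1a, the ligand-binding chain of the high-affinity receptor for immunoglobulin E, rose from 5.76 ± 0.454 to 27.6 ± 11.2 (2.26 ± 0.29, adjusted p = 0.00666), and stress replicate 3 had the smallest of the 3 stress values, 14.7. The log2 fold change of Fcer1a was 1.35 with stress replicate 3 alone (adjusted p = 0.00668) and 1.55 with the macrophage covariate (adjusted p = 0.00258). Other large rises were those of Ctsj, a cathepsin gene (3.04 ± 0.35), and Cntn4, a contactin (2.72 ± 0.27). Further rises were those of Ptpn3, a tyrosine phosphatase (2.13 ± 0.26), Tll1, an astacin-family metalloprotease (2.06 ± 0.19), Sema3e, a semaphorin (2.04 ± 0.25), Qpct, glutaminyl cyclase (2.01 ± 0.13), and Dusp14, a dual-specificity phosphatase (1.65 ± 0.25). Ctla2a, a cysteine protease inhibitor gene, was also called higher (1.66 ± 0.23), but 15.9% of its transcript 75-mers occur in another annotated gene. Its value is therefore uncertain. All of these calls held when any one library was left out. Fa2h, a fatty acid hydroxylase, had the largest fold among them (3.34 ± 0.60, adjusted p = 0.019). Its call ended without control replicate 2 (adjusted p = 0.0878), control replicate 3 (0.0684) or stress replicate 2 (0.0579). Fa2h was at 2.28 with the macrophage covariate (adjusted p = 0.0467), and did not pass with stress replicate 3 alone (2.03, 0.123), the Y-to-Xist covariate (2.48, 0.073) or limma-voom (3.25, 0.051).

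Sox4, a transcription factor of immature cells, fell by 1.19 on the log2 scale (SE 0.17, adjusted p = 0.00912), from 16.6 ± 4.15 to 7.30 ± 0.178 CPM. In the annotation 54.6% of its exon length is overlapped by a gene on the opposite strand. The non-muscle myosin gene Myh10 fell from 14.7 ± 1.57 to 8.33 ± 0.92, and Nes, encoding the intermediate filament nestin, fell from 12.9 ± 0.955 to 7.48 ± 1.05. Fmnl3, a formin, fell from 18.9 ± 1.33 to 11.2 ± 1.47, and Gdpd5 from 7.29 ± 0.181 to 4.36 ± 0.486. The calls of these 5 genes held when any one library was left out. Il2ra, the interleukin 2 receptor alpha chain, had the largest negative value (-5.69 ± 1.21, adjusted p = 0.0323). Its controls were uneven, at 26.0, 7.0 and 0.828 CPM in replicates 1, 2 and 3, against 0.217 ± 0.0689 in the stress libraries. The call held without control replicate 1 (adjusted p = 0.043), control replicate 3 (0.00766) or stress replicate 3 (0.0247). It ended without control replicate 2 (adjusted p = 0.0925), stress replicate 1 (0.101) or stress replicate 2 (0.129). Il2ra did not pass with limma-voom (-4.78, 0.275) or the Y-to-Xist covariate (-6.42, 0.0906). It passed with the macrophage covariate (-8.62, 0.0091) and the replicate block (-5.24, 0.0188). With stress replicate 3 alone, 1 library, it was at -5.40. The remaining genes among the largest falls, Fads2, Fam71a, Nuak1, Treml2, Gpr157 and Pald1, had log2 fold changes from -1.24 to -0.76. Each lost its call in at least 3 of the 6 fits that left out 1 library, with adjusted p-values up to 0.175.

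In all, 1035 of 16716 genes tested passed an adjusted p of 0.05, 725 higher and 310 lower after prenatal stress, and 4150 genes had an unadjusted p under 0.05. Of the genes called, 134 rose and 22 fell by more than 2-fold, and 956 of the 1035 were protein coding. The 3 stress libraries lay on one side of all 3 controls in 5107 genes, 30.6% of those tested, where chance gives 10% on average over all splits. Genes vary together, so the share in 1 split can lie far from 10% by chance, and this is not a test. The count changed with whichever library was left out: it was 460, 226 and 389 without control replicates 1, 2 and 3. Without stress replicates 1 and 2 it was 459 and 196, while without stress replicate 3 it rose to 2647. Scaling by library totals alone gave 2085 genes, of which 26.5% were higher, against 70.0% with TMM factors. That scaling moves the median of all genes to -0.119 on the log2 scale, and the fold changes here are relative to TMM.

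**Figure D1:**
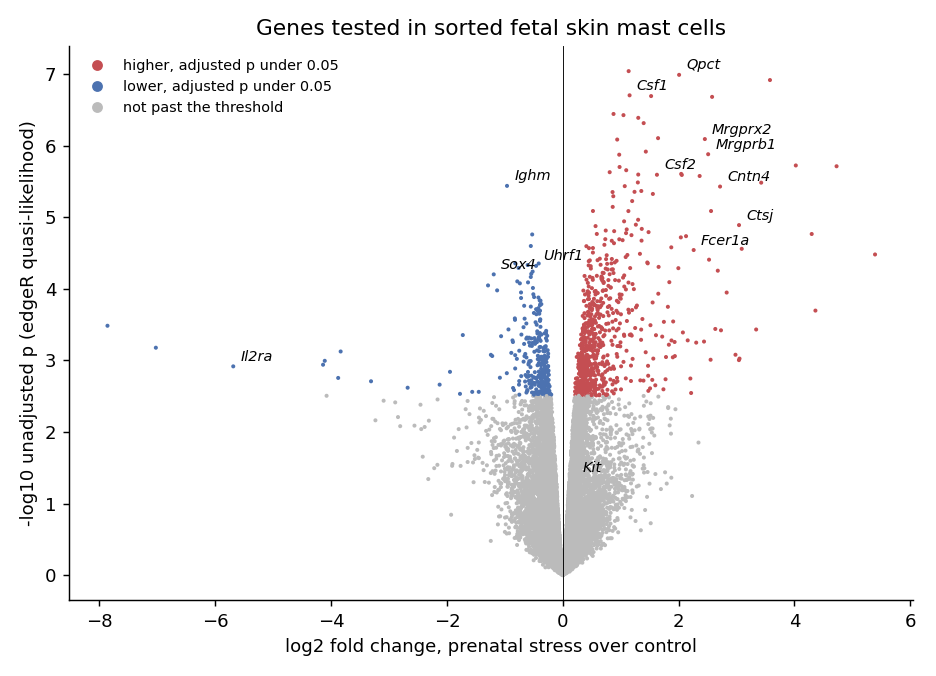
Each point is one of 16716 genes, by log2 fold change of prenatal stress over control on the x axis and -log10 of the unadjusted p-value on the y axis. Red points are the 725 genes called higher and blue points the 310 called lower, and named genes are marked, including Kit, which was not called.

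Of the 5 genes by which the cells were sorted, 1 was called. Kit was at 1818 ± 158 CPM in the controls and 2126 ± 220 after prenatal stress (log2 fold change 0.23 ± 0.10, adjusted p = 0.187), and Ptprc, which encodes CD45, was at 453 ± 9.35 and 491 ± 26.1 (adjusted p = 0.278). Il1rl1, which encodes ST2, was called higher (0.45 ± 0.10, adjusted p = 0.0312). Its call ended when any one library other than stress replicate 3 was left out (adjusted p from 0.0708 to 0.113). Adgre1, which encodes F4/80, was at 409 ± 29.2 and 305 ± 87.1 (adjusted p = 0.161), and Fcgr1, which encodes CD64, at 78.9 ± 6.27 and 66.9 ± 9.58 (adjusted p = 0.194). Transcripts of both genes used to exclude macrophages were present in every library.

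Macrophage transcripts were abundant and differed between libraries. Of the 16 measured members of the macrophage and monocyte list, 1 fell, none rose and 15 did not pass. The list as a set was lower (median log2 fold change -0.34, camera adjusted p = 0.00114, adjusted p = 0.615 with an estimated correlation). The gene that fell was Cx3cr1, the fractalkine receptor, from 430 ± 32.2 to 295 ± 19.1 CPM (adjusted p = 0.00912). It was at 310 CPM in stress replicate 3, below the controls at 395, 439 and 457. Where that library is said below to be at the control level, this holds for the list and not for each member. The mannose receptor gene Mrc1 was at 2159, 2387 and 2340 CPM in control replicates 1, 2 and 3, and at 1693, 1408 and 2729 in stress replicates 1, 2 and 3. Csf1r, the receptor of macrophage colony-stimulating factor, was at 1114, 1279 and 1252 in the controls and at 786, 669 and 1143 in the stress libraries. The mean log2 level of the list was 7.91, 8.11 and 8.10 in the controls and 7.66, 7.55 and 8.05 in stress replicates 1, 2 and 3 (exact two-sided permutation test, p = 0.2, where 3 against 3 cannot go below 0.1). Without stress replicate 3, the library at the control level, 2647 genes passed, and with stress replicate 3 alone against the controls, a comparison chosen after the data were seen, 171 passed, 148 of them higher. With the list mean as a covariate, also chosen after the data were seen, 394 genes passed, 300 higher and 94 lower, and 299 of them were among the 1035. Without the covariate 310 genes were called lower. A lower macrophage share might lower genes that macrophages express, and this was not tested for the genes called lower.

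**Figure D2:**
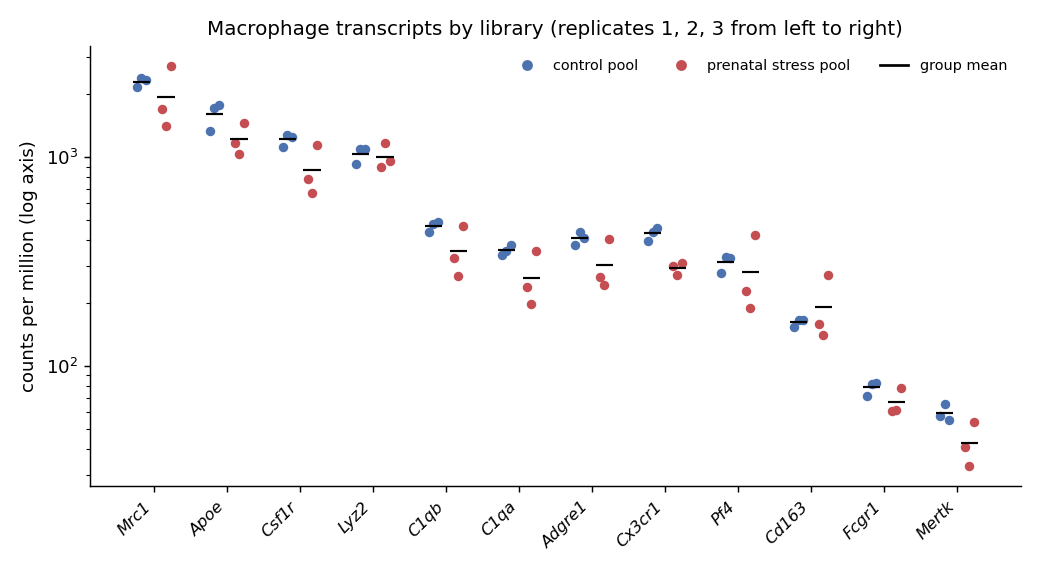
Levels in CPM (log axis) of 12 members of the macrophage list in each library, with replicates 1, 2 and 3 from left to right within a group and black bars at the group means. Stress replicates 1 and 2 lie below all controls for Mrc1, Csf1r, C1qa and Adgre1, and stress replicate 3 lies above both of them for each of these genes; Csf1r, for example, is at 786, 669 and 1143 CPM.

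Part of the granule genes of mast cells rose. Of 18 measured protease and granule content genes, 7 rose, none fell and 11 did not pass. There were 11 higher and 0 lower when adjusted over the list alone (median log2 fold change 0.40, camera adjusted p = 1.25e-04, adjusted p = 0.615 with an estimated correlation). Mcpt4, a chymase of connective tissue mast cells, rose from 1620 ± 221 to 3335 ± 669 CPM (1.04 ± 0.15, adjusted p = 0.00946). This call held when any one library was left out. Cpa3, mast cell carboxypeptidase and the most abundant gene of the list, rose from 24736 ± 2610 to 36202 ± 4551 (adjusted p = 0.0286), and the chymase gene Cma1 rose from 15205 ± 1422 to 20065 ± 1742 (adjusted p = 0.0463). Both of these calls ended when any one library other than stress replicate 3 was left out, with adjusted p from 0.0575 to 0.0864 for Cpa3 and from 0.073 to 0.141 for Cma1. Hdc, the histamine-forming enzyme, was at 13589 ± 1893 and 17948 ± 682 (adjusted p = 0.0562), and the tryptase gene Tpsb2 at 6879 ± 605 and 9416 ± 1382 (adjusted p = 0.0539). The list took 6.92% ± 0.515 of all counts in the controls and 8.92% ± 0.747 in the stress libraries (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allows; adjusted over 4 classes, 0.133). With stress replicate 3 alone, 1 library whose macrophage list mean was at the control level, the median was 0.22, against 0.40 with all libraries. With the macrophage covariate in all 6 libraries the granule list passed (median 0.27, camera adjusted p = 0.0408).

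Surface receptor and identity genes of mast cells rose in part. Of 25 measured, 14 rose, none fell and 11 did not pass. There were 19 higher and 1 lower when adjusted over the list alone. The list median was 0.44 (camera adjusted p = 2.59e-11, adjusted p = 0.578 with an estimated correlation). Beside Mrgprb1 and Fcer1a, Mrgprb2, the receptor for basic secretagogues, rose from 98.6 ± 9.85 to 243 ± 40.0 CPM (1.3 ± 0.12, adjusted p = 0.0017), and Mrgprb8 from 3.33 ± 0.364 to 6.21 ± 0.436 (0.90 ± 0.12, adjusted p = 0.00803). Csf2rb2, a beta chain of the interleukin 3 receptor, had a log2 fold change of 0.62 ± 0.10 (adjusted p = 0.014). The call ended without control replicate 3 (adjusted p = 0.0508) or stress replicate 2 (0.0613). Of its transcript 75-mers 10.6% are shared with Csf2rb, so both genes are uncertain. The transcription factor gene Gata2 was at 1386 ± 148 and 1661 ± 169 (adjusted p = 0.155). With stress replicate 3 alone the list median was 0.30, where the macrophage list median was -0.02. That is 1 library, so it measures no spread between stress pools.

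**Figure D3:**
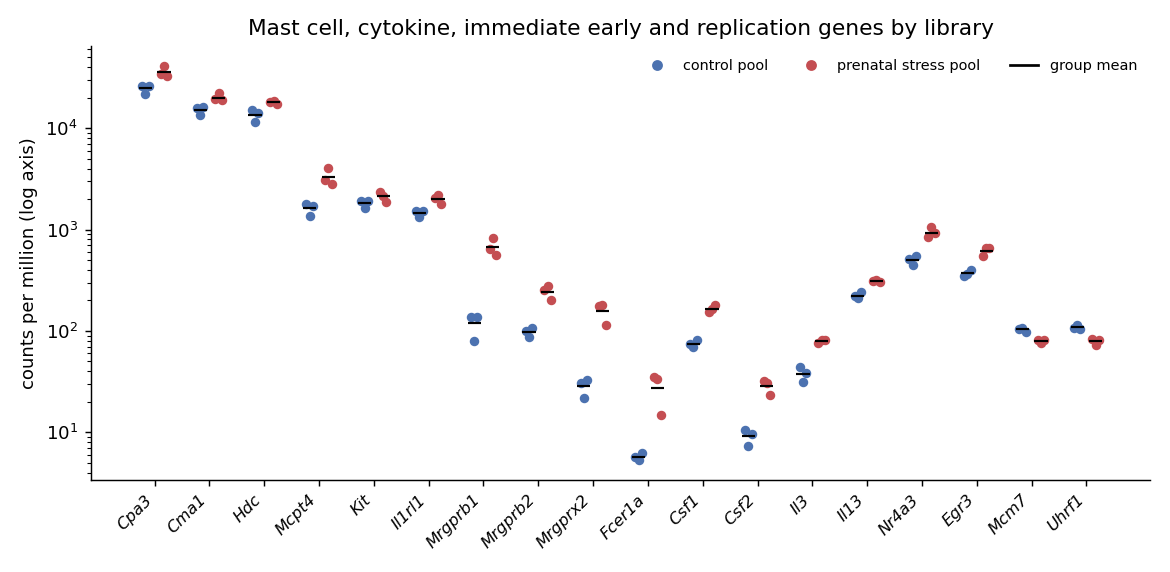
Levels in CPM (log axis) of 18 named genes, with 1 point per library and black bars at the group means; control pools are blue and prenatal stress pools red. The stress pools of Mrgprb1 lie at 562 to 820 against 80.3 to 138 in the controls, while those of Kit overlap the controls.

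Among genes downstream of the immunoglobulin E receptor and KIT, and those of granule release, most did not pass. In the signalling list of 32 genes 6 rose, 1 fell and 25 did not pass. There were 13 higher and 2 lower when adjusted over the list alone. Its median log2 fold change was 0.13 (camera adjusted p = 0.00834, adjusted p = 0.627 with an estimated correlation). Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, rose from 133 ± 6.28 to 182 ± 4.61 CPM (adjusted p = 0.00644), and this call held when any one library was left out. The adaptor gene Gab2 rose by 0.67 ± 0.12 on the log2 scale. The call of Gab2 ended without control replicate 3 (adjusted p = 0.0599), stress replicate 1 (0.058) or stress replicate 2 (0.0757). The gene that fell, chosen after its value was seen, was Pik3cd (-0.31, adjusted p = 0.028). Its call ended without any one control (adjusted p from 0.0893 to 0.0953) or without stress replicate 2 (0.0906). In the degranulation list 3 of 23 genes rose, none fell and 20 did not pass. Counts were 6 higher and 0 lower when adjusted over the list alone. As a set it had a median of 0.12 (camera adjusted p = 0.00107, adjusted p = 0.615 with an estimated correlation). The 3 were Rab27b and Rabgef1, which act in vesicle traffic, and Unc13b, a priming factor. Each lost its call in at least 4 of the 6 fits that left out 1 library, with adjusted p up to 0.141. With stress replicate 3 alone the signalling list did not pass (median 0.08, adjusted p = 0.0822), while with the macrophage covariate in all 6 libraries it did (0.07, 0.046).

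Some cytokine genes rose. Of 27 cytokine and growth factor genes measured, 11 rose, 2 fell and 14 did not pass. There were 14 higher and 2 lower when adjusted over the list alone. Over its members the median was 0.38 (camera adjusted p = 1.23e-05, adjusted p = 0.578 with an estimated correlation). Csf1, macrophage colony-stimulating factor, rose from 74.7 ± 5.96 to 166 ± 13.3 CPM (1.15 ± 0.08, adjusted p = 5.78e-04). Csf2, granulocyte-macrophage colony-stimulating factor, rose from 9.25 ± 1.65 to 28.6 ± 4.56 (1.63 ± 0.15, adjusted p = 0.0017), and Il3 from 37.8 ± 6.09 to 79.5 ± 2.72 (1.07 ± 0.11, adjusted p = 0.002). Tnfsf14, which encodes LIGHT, rose from 21.4 ± 1.05 to 39.4 ± 1.79, and the type 2 cytokine gene Il13 from 224 ± 15.2 to 313 ± 9.84 (0.48 ± 0.07, adjusted p = 0.00822). These 5 calls held when any one library was left out. Il1b was at 373 ± 27.6 and 487 ± 105 (adjusted p = 0.123) and Lif at 139 ± 25.7 and 169 ± 33.2 (adjusted p = 0.308). The 2 genes that fell, named after their values were seen, were Pdgfb (-0.72, adjusted p = 0.037) and Il16 (-0.53, adjusted p = 0.048). Both calls ended when any one library other than stress replicate 3 was left out, with adjusted p up to 0.193. The list went in the same direction with stress replicate 3 alone, which is 1 library.

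Chemokine genes did not move as a set: 1 of 20 rose, none fell and 19 did not pass. There was 1 higher and 0 lower when adjusted over the list alone (median 0.12, camera adjusted p = 0.261). The gene that rose was Ccl1, a ligand of CCR8, from 47.7 ± 4.92 to 91.5 ± 2.4 CPM (0.94 ± 0.08, adjusted p = 0.00105). This call held when any one library was left out. Cxcl2 was at 334 ± 52.7 and 423 ± 159 (adjusted p = 0.385) and Ccl2 at 220 ± 27.5 and 264 ± 92.6 (adjusted p = 0.475). Of 14 eicosanoid genes, 2 rose, 1 fell and 11 did not pass. Counts were 3 higher and 3 lower when adjusted over the list alone (median -0.15, camera adjusted p = 0.471). Ptgs2, the inducible cyclooxygenase, rose from 244 ± 31.5 to 388 ± 21.1 in a call that held when any one library was left out. Ptgs1, the constitutive cyclooxygenase, fell from 52.8 ± 8.04 to 32.2 ± 5.0, and Ptgds rose from 0.762 ± 0.208 to 2.65 ± 1.33. Ptgs1 was at 29.0, 29.6 and 38.0 CPM in stress replicates 1, 2 and 3, highest where the macrophage list was highest. Whether a lower macrophage share contributed to its fall was not tested. The call of Ptgs1 ended without control replicate 2 (adjusted p = 0.085), control replicate 3 (0.0601), stress replicate 1 (0.0678) or stress replicate 2 (0.0865). That of Ptgds ended when any one library other than stress replicate 3 was left out (adjusted p from 0.0501 to 0.132), and Ptgds was at 1.02 with the macrophage covariate (adjusted p = 0.0963) against 1.78 without it.

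Receptors for neuropeptides, neurotransmitters and stress hormones passed narrowly as a set, with 2 of 20 measured genes higher, none lower and 18 not passing, and 2 higher and 1 lower when adjusted over the list alone. The list median was 0.16 (camera adjusted p = 0.0331, adjusted p = 0.578 with an estimated correlation). The 2 were Mrgprb2 and Ramp1, a subunit of the receptor for calcitonin gene-related peptide, which rose from 18.8 ± 0.689 to 28.5 ± 2.69 CPM (0.60 ± 0.08, adjusted p = 0.00796). Both calls held when any one library was left out. Nr3c1, the glucocorticoid receptor gene, was at 276 ± 23.4 and 319 ± 30.0 (adjusted p = 0.18). The list did not pass with no filter on low counts (adjusted p = 0.0525), with the stricter filter (0.093), with the macrophage covariate (0.0714) or with stress replicate 3 alone (0.105). The glucocorticoid response list did not pass: 5 of 29 genes rose, none fell and 24 did not pass. Counts were 10 higher and 4 lower when adjusted over the list alone (median 0.21, camera adjusted p = 0.0555, adjusted p = 0.578 with an estimated correlation). It passed with library totals alone (adjusted p = 0.0188), with no filter on low counts (0.0135) and with the Y-to-Xist covariate (0.0331). It also passed without control replicate 2 (0.0439), control replicate 3 (0.0412), stress replicate 1 (0.0285) or stress replicate 2 (0.0258), and with the macrophage covariate (0.00446). Stress replicate 3 alone, which is 1 library, gave the same direction. Its members Tsc22d3 (0.38 ± 0.07, adjusted p = 0.0212), Nfkbia (0.61 ± 0.11, adjusted p = 0.0214) and Cebpb (0.70 ± 0.13, adjusted p = 0.0236) rose. Each lost its call in at least 3 of the 6 fits that left out 1 library, with adjusted p up to 0.0964.

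Immediate early genes are induced within minutes of cell activation. Of 28 measured, 14 rose, 1 fell and 13 did not pass. Counts were 17 higher and 3 lower when adjusted over the list alone. Its median log2 fold change was 0.37 (camera adjusted p = 2.47e-07, adjusted p = 0.578 with an estimated correlation). The nuclear receptor gene Nr4a3 rose from 506 ± 53.3 to 935 ± 110 CPM (0.89 ± 0.10, adjusted p = 0.00522), Egr3 from 373 ± 27.5 to 620.5 ± 63.6 (0.73 ± 0.09, adjusted p = 0.00565) and Ier2 from 214 ± 13.1 to 307 ± 13.5. These calls held when any one library was left out, whereas that of Junb (0.94 ± 0.15, adjusted p = 0.013) ended without control replicate 2 (adjusted p = 0.0686). The gene that fell, named after its value was seen, was Myc (-0.58, adjusted p = 0.03), a call that ended when any one library other than stress replicate 3 was left out (adjusted p from 0.0581 to 0.131). The heat shock list did not move as a set (1 higher, 1 lower and 17 not passing of 19, and 2 and 2 when adjusted over the list alone; median -0.01, camera adjusted p = 0.998), and its inducible member Hspa1b was at 495 ± 80.7 and 804 ± 108 (adjusted p = 0.0209). Hspa1b shares 55.8% of its transcript 75-mers with Hspa1a. Its call ended without control replicate 1 (adjusted p = 0.0651), control replicate 2 (0.101), stress replicate 1 (0.0627) or stress replicate 2 (0.0787).

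Of 21 nuclear factor kappa B response genes, 4 rose, none fell and 17 did not pass. Counts were 6 higher and 0 lower when adjusted over the list alone. As a set it had a median of 0.20 (camera adjusted p = 0.00224, adjusted p = 0.615 with an estimated correlation). The 4, Nfkbia, Nfkbiz, Nfkbib and Tnfaip3, include inhibitors of that pathway. Each lost its call in at least 4 of the 6 fits that left out 1 library, with adjusted p up to 0.17. Without stress replicate 3 the list did not pass (adjusted p = 0.233). In the type I interferon list 1 of 29 genes rose, Ifit3, and 28 did not pass. Counts were 2 higher and 0 lower when adjusted over the list alone. Over its members the median was 0.19 (camera adjusted p = 0.0013, adjusted p = 0.627 with an estimated correlation). Ifit3 shares 41.1% of its transcript 75-mers with Ifit3b and is uncertain. This call ended without any one control or stress replicate 2 (adjusted p from 0.0793 to 0.12). The list did not pass without control replicate 1 (adjusted p = 0.0544) or stress replicate 3 (0.104).

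Some genes of DNA replication and division fell. Of 37 measured, 9 fell, none rose and 28 did not pass. Counts were 28 lower and 1 higher when adjusted over the list alone. The list median was -0.20 (camera adjusted p = 9.56e-12, adjusted p = 0.597 with an estimated correlation). Mcm7, a subunit of the replicative helicase, fell from 104 ± 5.46 to 80.1 ± 2.78 CPM (adjusted p = 0.0137), and Tyms, thymidylate synthase, fell from 38.6 ± 1.58 to 29.2 ± 1.91 (adjusted p = 0.0152). The call of Mcm7 ended without control replicate 2 (adjusted p = 0.0614) or stress replicate 2 (0.064). That of Tyms ended without control replicate 2 (0.0729), control replicate 3 (0.0562) or stress replicate 2 (0.0576). Of 34 DNA methylation and chromatin genes 2 fell, none rose and 32 did not pass, and 2 were lower and 0 higher when adjusted over the list alone. Its median log2 fold change was -0.08 (camera adjusted p = 0.0215, adjusted p = 0.627 with an estimated correlation). The 2 were Uhrf1, which fell from 109 ± 4.04 to 79.1 ± 4.95 in a call that held when any one library was left out, and Dnmt1, the maintenance methyltransferase, from 206 ± 0.698 to 166 ± 10.7, whose call ended without any one control or stress replicate 2 (adjusted p from 0.0822 to 0.0976). Both are known to act at replicating DNA. Of the transcript 75-mers of Mcm7 and Uhrf1, 9.5% and 9.0% occur in other annotated genes, so these values are uncertain. The chromatin list did not pass without control replicate 1 (adjusted p = 0.0937) or stress replicate 3 (0.177). With stress replicate 3 alone, which is 1 library, the proliferation list median was -0.15.

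The integrin and adhesion list went both ways, with 3 of 26 genes higher, 3 lower and 20 not passing, and 4 and 4 when adjusted over the list alone (median -0.03 and mean 0.01, camera adjusted p = 0.998). Itga2, the collagen-binding alpha 2 integrin, rose from 143 ± 23.8 to 365 ± 50.0 CPM (1.36 ± 0.14, adjusted p = 0.00218). This call held when any one library was left out. Itgal fell from 120 ± 3.13 to 92.2 ± 6.13. Its call ended without control replicate 2 (adjusted p = 0.0615). Itga6 fell by 0.67 and Itgb5 by 0.53 on the log2 scale. Itga6 was at 43.0, 40.0 and 58.8 CPM in stress replicates 1, 2 and 3, and Itgb5 at 37.3, 34.2 and 46.5. These 2 genes were thus highest where the macrophage list was highest, and a part of the macrophage share was not tested. Both calls ended when any one library other than stress replicate 3 was left out, with adjusted p up to 0.107. Of 28 glycolysis and hypoxia genes 3 rose, none fell and 25 did not pass. Counts were 3 higher and 1 lower when adjusted over the list alone (median 0.01, camera adjusted p = 0.819). Ndrg1, a hypoxia-responsive gene, rose from 315 ± 55.0 to 777 ± 117 (1.3 ± 0.15, adjusted p = 0.00431) in a call that held when any one library was left out.

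The other pathway lists showed few or no calls. The mitochondrially encoded mRNAs were higher as a set (2 higher, none lower and 11 not passing of 13, the same counts when adjusted over the list alone; median 0.13, camera adjusted p = 0.0165, adjusted p = 0.615 with an estimated correlation). The 2 called, mt-Atp6 and mt-Co3, share 99.5% and 99.9% of their transcript 75-mers with other annotated genes and are uncertain. The set did not pass with library totals alone (adjusted p = 0.0879), without control replicate 1 (0.0544) or without stress replicate 3 (0.124). These mRNAs took 1.64% of counts in both groups (exact two-sided permutation test, p = 0.9). The unfolded protein list had 0 of 24 genes called in edgeR (camera adjusted p = 0.765), also when adjusted over the list alone, and cytosolic ribosomal proteins 0 of 54 (median 0.04, camera adjusted p = 0.0724). Antigen presentation (1 higher and 1 lower of 19, or 4 and 3 when adjusted over the list alone; camera adjusted p = 0.998), oxidative phosphorylation (1 higher of 32, or 0 when adjusted over the list alone; camera adjusted p = 0.998) and cholesterol synthesis (1 higher of 23, or 1 when adjusted over the list alone; camera adjusted p = 0.279) did not move as sets. Ribosomal protein mRNAs took 3.81% ± 0.0783 of counts in the controls and 3.61% ± 0.102 in the stress libraries (exact two-sided permutation test, p = 0.1).

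**Figure D4:**
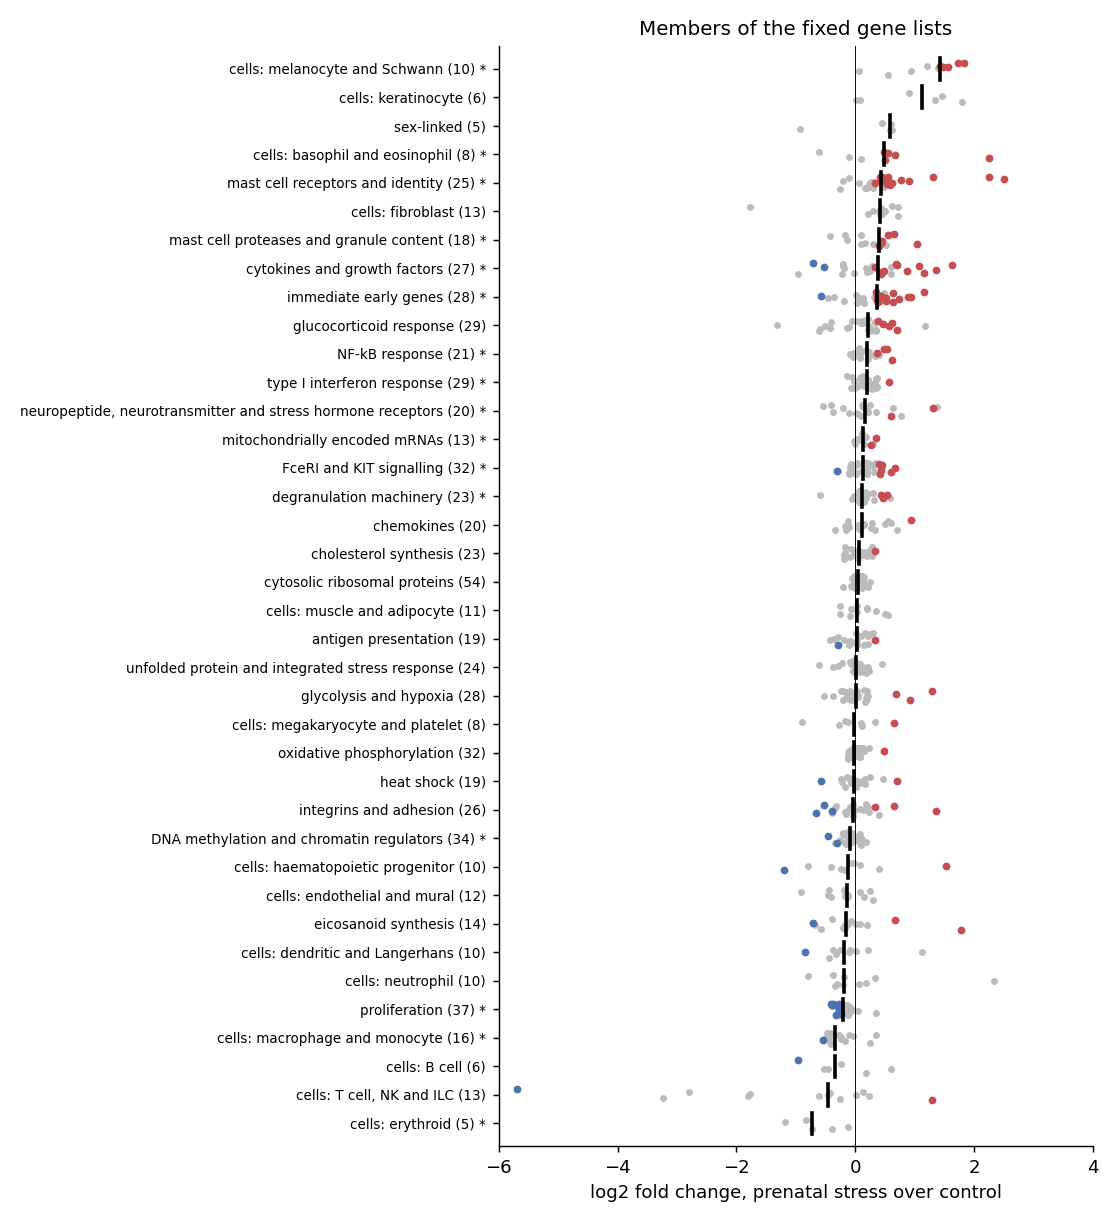
Log2 fold change of each measured member of the 38 fixed gene lists, sorted by list median (black bars), with the number of measured genes in parentheses and an asterisk where the camera adjusted p was under 0.05. Red and blue points are members called higher and lower; the pigment cell list has the highest median, 1.42, and the erythroid list the lowest, -0.73.

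Markers of several other cell types were measured to describe what else the sorted cells held. The melanocyte and Schwann cell list had 5 of 10 genes higher, none lower and 5 not passing. Counts were 6 higher and 0 lower when adjusted over the list alone. As a set it had a median of 1.42 (camera adjusted p = 7.97e-05, adjusted p = 0.615 with an estimated correlation). The pigment synthesis genes Dct and Pmel rose from 8.01 ± 2.08 to 23.8 ± 11.5 and from 5.40 ± 1.09 to 14.6 ± 6.49 CPM (adjusted p = 0.0286 and 0.0263). Tyrp1 and Tyr rose from 0.927 to 3.30 and from 1.23 to 3.44. The call of Dct ended without control replicate 2 (adjusted p = 0.144), control replicate 3 (0.0943), stress replicate 1 (0.0683) or stress replicate 2 (0.0672). The calls of Pmel, Tyrp1 and Tyr each ended in at least 3 of the 6 such fits, with adjusted p up to 0.147. That of Mlana, named after its value was seen, ended without any one library other than stress replicate 3 (adjusted p from 0.0624 to 0.165). Of 8 basophil and eosinophil genes 5 rose, none fell and 3 did not pass, also when adjusted over the list alone. Over its members the median was 0.49 (camera adjusted p = 0.0013, adjusted p = 0.578 with an estimated correlation). They include Fcer1a and Cd200r3, which the mast cell list holds too. Mcpt8, a basophil protease, was at 17.2 ± 1.43 and 24.3 ± 1.88 (adjusted p = 0.0169). The call ended without control replicate 1 (adjusted p = 0.0531), control replicate 2 (0.075), stress replicate 1 (0.0538) or stress replicate 2 (0.0712). The 5 erythroid genes measured were lower as a set with 0 called in edgeR. The list median was -0.73 (camera adjusted p = 0.0441, adjusted p = 0.627 with an estimated correlation), or 1 lower when adjusted over the list alone. They took 0.00137% of counts in the controls and 7.08e-04% in the stress libraries (exact two-sided permutation test, p = 0.1), a difference carried mostly by control replicate 2 at 0.00217%. The set did not pass without control replicate 2 (adjusted p = 0.0947) or stress replicate 2 (0.0793), nor with upper-quartile factors (0.0504), library totals alone (0.195), protein-coding genes only (0.063), the macrophage covariate (0.314) or stress replicate 3 alone (0.562).

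Lymphoid and progenitor lists held few calls, some of them large. Ighm, the immunoglobulin M heavy chain, fell from 34.6 ± 3.16 to 17.8 ± 1.76 CPM (-0.96 ± 0.09, adjusted p = 0.002), the one gene of 6 called in the B cell list (camera adjusted p = 0.108; 2 lower and 0 higher when adjusted over the list alone). In the list for T cells, natural killer cells and innate lymphoid cells, Il7r rose from 22.0 ± 4.01 to 54.1 ± 4.79 (1.3 ± 0.13, adjusted p = 0.00196), Il2ra was called lower and 11 of 13 genes did not pass. With adjustment over the list alone, 1 was higher and 7 were lower, so the fall was not confined to Il2ra. The list median was -0.45 and its mean -1.18 (camera adjusted p = 0.0574, adjusted p = 0.627 with an estimated correlation). Among 10 progenitor genes Ly6a, which encodes SCA-1, rose from 4.05 ± 0.377 to 11.7 ± 0.928 (1.53 ± 0.11, adjusted p = 5.78e-04) while Sox4 fell, with the same 2 calls when adjusted over the list alone (median -0.13, though camera's direction was up; adjusted p = 0.998). The calls of Ighm, Il7r and Ly6a held when any one library was left out. The lists for keratinocytes (0 of 6 called in edgeR, median 1.13, camera adjusted p = 0.521), fibroblasts (0 of 13, median 0.42, 0.0555), endothelial and mural cells (0 of 12, median -0.14, 0.441), neutrophils (0 of 10, median -0.20 and mean 0.07, 0.998) and muscle and adipocytes (0 of 11, median 0.03, 0.998) had no member called, also when adjusted over the list alone. The dendritic and Langerhans list (1 lower of 10, or 1 higher and 1 lower when adjusted over the list alone; 0.419) and the megakaryocyte list (1 higher of 8, or 2 when adjusted over the list alone; 0.88) did not pass.

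The sex mix of the pools differed between libraries. The log2 ratio of Y-linked to Xist counts was -1.97, -1.32 and -3.27 in control replicates 1, 2 and 3, and 2.80, -1.61 and -1.36 in stress replicates 1, 2 and 3 (exact two-sided permutation test, p = 0.3). None of the 5 measured sex-linked genes was called in edgeR, also when adjusted over the list alone (camera adjusted p = 0.223). With that ratio as a covariate 410 genes passed, 329 higher and 81 lower, among them Mrgprb1 (2.66, adjusted p = 0.00925), Fcer1a (2.05, adjusted p = 0.0377) and Csf2 (1.57, adjusted p = 0.019), while Cpa3 did not pass (0.64, adjusted p = 0.0515).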

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

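The share of reads that did not align to a single place was 8.84% in the mean of the prenatal stress libraries (8.70%, 9.0% and 8.83% in replicates 1, 2 and 3) and 8.51% in the mean of the controls (8.49%, 8.55% and 8.49%). It stands out because these reads are in no gene count, and each stress library lay above each control (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allows). No explanation of it was tested.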

How the results depend on the processing

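No result that passed its test in either setting changed direction under an alternative. For lists the direction is camera's. With no filter the basophil and eosinophil list still passed as higher, though its median fell to -0.01 as genes with few counts entered it. The macrophage covariate and stress replicate 3 alone were chosen after the data were seen; the other alternatives were fixed before. The 1035 genes called, 725 higher and 310 lower, stayed within 1.5 times with RLE or upper-quartile factors, the stricter filter, limma-voom, protein-coding genes only, and without haemoglobin, mitochondrial and sex-linked genes (997 to 1206 genes). With library totals only, 2085 genes passed, 553 higher and 1532 lower, 853 of them among the 1035; that scaling moves the median of all genes to -0.119. With no filter 1933 passed (1123 higher, 810 lower), with DESeq2 1876 (1199 and 677), and with limma-voom and sample weights 1591 (985 and 606); the cause was not tested. A tested change of more than 1.5-fold left 45 genes, 45 higher and 0 lower, with 417 at an unadjusted p under 0.05, by its own construction a stricter hypothesis. The Y-to-Xist covariate gave 410 genes (329 and 81), the macrophage covariate 394 (300 and 94), and stress replicate 3 alone 171 (148 and 23); the latter has fewer samples, and the cause was not tested for the covariates. Over the 6 fits without 1 library, the total ran from 196 to 2647, higher calls from 168 to 1330 and lower calls from 23 to 1317. The 1035 genes kept their sign in each of these fits, which was close to fixed in advance. In all 1035 the 3 stress libraries lay on one side of the 3 controls, so leaving out 1 library could hardly reverse a sign. Leaving out stress replicate 3 raised the count and leaving out any other library lowered it.

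Replicate numbers did not pair the samples: deviations from the group means correlated at 0.095, -0.019 and 0.068 between same-numbered samples, and not every sample correlated best with its own number. With the replicate block 622 genes passed, 469 higher and 153 lower, 567 of them among the 1035.

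The list count of 16 ran from 13 to 20 under the alternatives with a preset correlation. Lists that did not pass in the main fit but did under at least one alternative were those for glucocorticoid response, chemokines, unfolded protein response, oxidative phosphorylation, ribosomal proteins, fibroblasts, keratinocytes, T cells, B cells, endothelial cells, dendritic cells and sex-linked genes. The count was 0 with an estimated correlation and 0 with fry for a change in one direction, which had 2 and 9 lists at an unadjusted p under 0.05. The former allows for the correlation of genes within a list, and the latter compares no list with other genes. Correlation alone does not account for the loss of calls. The neuropeptide receptor list had an estimated correlation of 0.00629, under the preset 0.01. Its unadjusted camera p still went from 0.013 with the preset to 0.0627 with the estimate. Changes of members in either direction, which fry also tests, are not in this count. Some lists that did not move as sets passed that test: heat shock (fry adjusted p = 0.00398), antigen presentation (0.00585), integrins (0.00914), chemokines (0.0171) and eicosanoids (0.0169). The nuclear factor kappa B (0.287), type I interferon (0.0794), macrophage (0.114) and erythroid (0.0975) lists did not pass it. Of the 100 named genes called, 59, 43 and 58 kept their call without control replicates 1, 2 and 3, and 59, 46 and 100 without stress replicates 1, 2 and 3. The granule and ribosomal protein shares kept the direction of their differences under the other denominator and without any one library. The mitochondrial difference of 0.00379% ran from -0.0252% to 0.0372% without 1 library, and that of the erythroid genes went from -6.58e-04% to -2.57e-04% without control replicate 2.

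At 51710555 to 74735139 counts per library the depth is alike between groups, and 3 pools per group limit the comparison. On simulated counts 48% of the genes changed by 1.5-fold and 94% of those changed by 4-fold were recovered. The simulation changed few genes and made 131 calls, against 1035 in the data. Its adjusted threshold was therefore stricter, and these shares need not carry over.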

Other observations

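The tests of the pigment genes and of the heat-induced genes were chosen after the result was seen, and those with stress replicate 3 alone and with the macrophage covariate used settings chosen after the data were seen, although the bound for the immediate early genes in stress replicate 3 alone was set before that value was computed. The tests of the sex mix and of the splits were written before.

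Of 25 receptor and identity genes of mast cells 14 were called higher in the stress libraries, and a lower macrophage share might raise them by dilution. The gate on F4/80 and CD64 would remove macrophages, and whether these transcripts came from macrophages or from the sorted mast cells was not tested. In stress replicate 3 alone, whose macrophage list median was -0.02, the median log2 fold change of the 25 genes was 0.30 (95% bootstrap interval over genes 0.18 to 0.40), and 3 of the 14 calls held. That is 1 library, and these intervals resample genes that vary together (estimated correlation 0.433), so they do not measure the spread between pools. With the macrophage covariate in all 6 libraries the median was 0.30 (0.19 to 0.42) against 0.44 (0.26 to 0.56) without it. With that covariate 7 of the 14 calls held, which argues against dilution as the whole cause for those genes, though it may account for part. The sex mix of the pools as the whole cause is argued against less firmly. With the Y-to-Xist covariate the median was 0.47 and 7 of the 14 calls held, the fewest that the bound set beforehand allowed. The ratio was 2.80 in stress replicate 1 and -3.27 to -1.32 in the other libraries, so the covariate mostly sets 1 library apart. A response of the mast cells to maternal stress stays open as a hypothesis, and the maturity of the cells, the litter and the day of sorting were not tested.

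Dct, Pmel, Tyrp1, Mlana and Tyr were higher after prenatal stress. Melanocytes among the sorted cells are a candidate source, since these cells carry KIT, although the gate on CD45 and ST2 would remove them. The median SD of the pairwise log2 ratios of the 5 genes was 0.39 against 0.95 for their levels, which decides nothing: the test was written after the list had been seen to rise, and a group difference common to the genes gives such values whatever their source. Their median log2 fold change was 1.34 above that of Kit. That comparison does not decide whether a higher overall share of mast cells raised them. Its bound was set after the values were seen, and Kit is a marker by which all the cells were sorted. In stress replicate 3 alone Dct and Pmel were at 0.78 and 0.81 (adjusted p = 0.152 and 0.113) against 1.56 and 1.43 in the full comparison. With the macrophage covariate they were at 0.76 and 0.77 (adjusted p = 0.033 and 0.0552), so their size depends on these choices. The most abundant of them, Dct, was at 21.2, 36.3 and 13.9 CPM in stress replicates 1, 2 and 3. Melanocytes and pigment genes expressed within mast cells both stay open.

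Of 28 immediate early genes 14 were called higher after prenatal stress, and a lower macrophage share might raise them by dilution. The list median was 0.37 (0.14 to 0.46) in the full comparison and 0.33 (0.22 to 0.48) with the macrophage covariate, which argues against dilution as the whole cause. In stress replicate 3 alone, 1 library, it was 0.33 (0.18 to 0.49). These intervals also resample genes and do not measure the spread between pools. A stronger response to the digestion of the tissue may contribute. The heat-induced genes Hspa1a, Hspa1b, Dnajb1 and Hsph1 had a median log2 fold change of 0.35, with values of 0.46, 0.70, 0.25 and -0.24, of which Hspa1b alone passed. Hspa1b shares 55.8% of its transcript 75-mers with Hspa1a, so these values are not independent. The heat shock list of 19 genes did not move as a set (median -0.01, camera adjusted p = 0.998). Its other called member, Hspb1, fell (-0.58, adjusted p = 0.0212 in edgeR), so whether digestion contributed is not settled. Activation in the skin and during preparation are both open.

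Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many genes: 1035 against a highest count of 0 for the others in edgeR. With 10 splits no share under 0.05 is possible.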
